A study of Mus musculus with 6 samples.

How the data were processed

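The series holds polyA RNA sequencing of tumours grown from 4T1 mammary carcinoma cells in the mammary fat pad of BALB/c mice, taken on day 6 after injection. There were 2 groups of 3 libraries, from WT and from Nod2-/- hosts, grouped by the genotype label and the letter of the title. The tissue label is breast tumour, while the extraction protocol in the labels speaks of liver, so a list of hepatocyte genes is given below. Libraries were made with a stranded mRNA kit, per the labels' protocols; whether counting used strand is not given in the sources used here, so genes that overlap or are antisense to others are uncertain.

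Per the submitters' processing notes, the tools were Trimmomatic 0.33, TopHat2 2.1.1 and DESeq2 (version not given), with the genome build GRCm38; the counter and annotation are not given in the sources used here. The deposited table holds 28459 genes, all of which had an entry of the same version in GENCODE M21, which gave symbols and coordinates. The deposited signal values were made by the authors by dividing the read count of each gene by 1 factor per library, a reading that rests on the values themselves since no header states it. In every library 100% of the values were whole multiples of what 1 read was worth, within 0.1 read, and the whole reads were recovered with a largest rounding error of 0.00536 in deposited units. The implied factors of the authors lay between 1.17 and 1.72 and were 1.40 to 1.49 times those DESeq2 computed from the recovered reads, with the higher ratios in Nod2-/- (1.47 to 1.49, against 1.40 to 1.43 in WT). Of all genes, 859 had 0 reads in the 6 libraries. Library totals were 15435144 to 18944076 reads; counting intervals and floors (3 reads) cover counting error only, since reads without molecular identifiers are not independent molecules.

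The test planned before the data were examined was edgeR's quasi-likelihood test on raw counts. Because the table holds normalised values, the test used was limma's moderated test with a mean trend on log2(value + 1), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Genes were kept with edgeR's filterByExpr on the recovered reads (minimum 10 reads, total 15), which left 18044. The planned edgeR test was run on the recovered reads as an alternative. R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0 were used. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. Replicates of a group differed by more than sampling noise (chi-square per degree of freedom of recovered reads from 12.2 to 117 over the 6 pairs within groups), so no library was counted as a copy of another.

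A set of 41 gene lists (cell types, pathways, RNA quality and neighbours of Nod2) was fixed before the data were examined, and 40 had at least 5 genes tested. Lists were tested with limma's camera (preset correlation 0.01, adjusted over 40 lists); camera with an estimated correlation and fry were alternatives. A listed symbol was matched to the gene of that name, and a symbol that GENCODE M21 does not use to the M21 gene with that synonym. An earlier matching also took Prg2 for Plppr3 and Csn2 for Cops2, which are other genes. It was corrected after the results had been seen, and the correction moved the list of mammary epithelium genes past camera's threshold (adjusted p 0.0352, against 0.0527 before), while no other list crossed it. With an estimated correlation the mammary list did not pass (camera adjusted p 0.614).

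Named genes follow a rule fixed with the lists: Nod2; the 12 genes of largest log2 fold change in each direction among those past the threshold, with a mean log2 CPM of at least 1 and no overlap between groups, leaving out predicted genes and pseudogenes; and up to 4 members with the smallest unadjusted p of each list. The rule was written for the planned edgeR test but was applied to limma's calls, fold changes and p-values. Of the 12 largest increases so named, edgeR did not call 6. Arl2bp and the few epidermal and melanocyte genes of the closing section fall outside the rule and were chosen after their values were seen. Alternatives fixed in advance were other scalings (DESeq2's size factors, upper quartile, library size), no filter, a filter of 1 CPM in 3 libraries, each library left out, the replicate number as a block, DESeq2, limma-voom, a threshold of 0.1 and an absolute log2 fold change of at least 1. edgeR was the planned test and became an alternative, run on the recovered reads, once the table was seen to hold normalised values. Added after seeing the data were TMM factors for limma, pseudocounts of 0.5 and 5, and WT replicate 1 alone against Nod2-/-. So were the adipocyte score as a covariate (for 2 lists also with an estimated correlation) and the earlier symbol matching.

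The test was tested on simulated data for Nod2-/- against WT (17690 genes tested, 200 changed). limma recovered 6% of genes changed 2-fold and 54% of those changed 4-fold, with 2 false calls among 62. DESeq2 recovered 29% and 86%, with 46 false among 161. camera called the shifted list and no unshifted one. Genes were simulated independently of each other, so this does not check camera on lists whose members vary together. The rates of recovery and of false calls need not carry over to the data either, where 3852 genes were called. The estimated correlation in the data was 0.941 for cell cycle and 0.812 for adipocyte genes. It was only -0.0186 for mammary epithelium and 0.0228 for mast cell genes. Their unadjusted camera p still rose from 0.0185 to 0.0627 and from 0.00739 to 0.0675 when the correlation was estimated. A call lost in that setting therefore does not by itself show that a list's members vary together.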

Results

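Tumours grown from 4T1 cells, a transplantable mammary carcinoma line of BALB/c mice, were compared by mRNA sequencing between WT hosts and hosts without Nod2, a cytosolic receptor for muramyl dipeptide from bacterial peptidoglycan. Each group held 3 libraries, from tumours taken on day 6 after injection into the mammary fat pad. The libraries held 18204687, 16135292 and 18906077 reads in WT and 18944076, 16979713 and 15435144 in Nod2-/-. No label says that each library came from a separate mouse, so the p-values measure only the spread between these samples, which may be technical. Levels are normalised read counts (mean ± SD, n = 3 per group), and log2 fold changes are Nod2-/- minus WT.

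Nod2 (chromosome 8, 88647315 to 88688474, GRCm38) had 60, 33 and 60 reads in WT and 41, 48 and 52 in Nod2-/-, or 3.29, 2.27 and 3.49 against 2.02, 2.68 and 3.12 CPM. Its log2 fold change was -0.27 (SE 0.292) and its adjusted p from limma 0.517. The 95% counting intervals ran from 22.7 to 77.2 reads in WT and from 29.4 to 68.2 in Nod2-/-. These counts cover the whole gene, the injected carcinoma cells carry an intact Nod2, and a knockout allele can be transcribed outside its deleted part. The level of Nod2 therefore does not check the genotype labels.

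As lists, genes of cell division and keratinised epidermis were higher in Nod2-/- tumours in limma's camera, and those of fat, peripheral nerve and the mitochondrial genome were lower, while with an estimated correlation 0 of 40 lists passed (smallest adjusted p 0.614). The mitotic kinase Plk1 rose from 53.3 ± 48.0 to 369 ± 74.4, and the adipokine Cfd fell from 46740 ± 4308 to 8850 ± 5269. The milk protein gene Csn3 fell from 633 ± 77.3 to 100.2 ± 6.29, and the suprabasal keratin Krt1 rose from 0.460 ± 0.400 to 467 ± 310.1. Of 18044 genes tested, 3852 passed the limma threshold, 1709 higher and 2143 lower in Nod2-/- (44.4% higher). With libraries scaled by their totals alone, 4818 passed, 3369 higher and 1449 lower (69.9% higher), and the median log2 fold change of all genes was 0.22 in place of -0.04. edgeR on the recovered reads called 3317, of which 3178 were shared, all with the same sign. Non-overlapping groups were seen for 7986 genes (44.3%). Chance gives 10% on average over splits, but a single split can lie far from that where genes vary together.

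The count depended on which library was left out. It was 9 without WT replicate 2, 20 without WT replicate 3, 0 without Nod2-/- replicate 2 and 32 without Nod2-/- replicate 3 (5165, 5132, 4887 and 5003 genes at an unadjusted limma p under 0.05), but 7682 without WT replicate 1 and 4202 without Nod2-/- replicate 1. Of the called genes 3795 had an adjusted p of 0.02 or more. Of the 119 genes named here that passed, 119 lost the call without Nod2-/- replicate 2, 112 without WT replicate 2, 110 without WT replicate 3 and 107 without Nod2-/- replicate 3, while 108 kept it without Nod2-/- replicate 1, and 0 changed sign in these fits. On the first principal component (72.2% of the variance), WT replicates 2 and 3 lay at -104 and -102, the Nod2-/- libraries at 43.4, 74.8 and 84.8, and WT replicate 1 at 2.46, nearer to each Nod2-/- library than to either WT library; its correlations were 0.96, 0.948 and 0.931 with the Nod2-/- libraries and 0.927 and 0.923 with WT replicates 2 and 3. Against WT replicate 1 alone, a comparison added after the data were seen, limma called 0 genes (3176 at an unadjusted p under 0.05). This fit has a single WT library, so its spread comes from the Nod2-/- libraries alone and its 0 is no test like those above; medians from it are given for the gene groups.

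**Figure D1:**
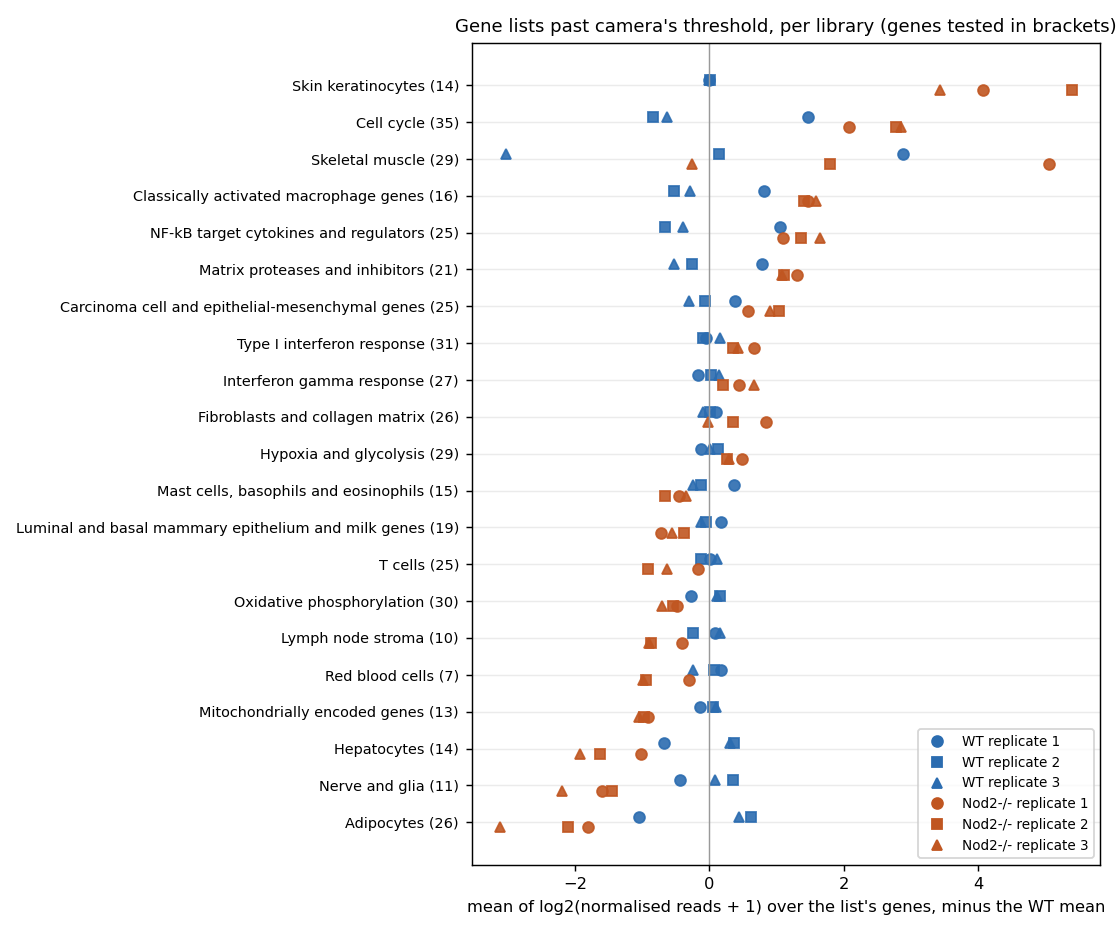
Each point is a library, placed by the mean log2(normalised reads + 1) of a list's tested genes minus the WT mean (horizontal axis), for the 21 lists past camera's threshold (vertical axis); colour is the genotype and shape the replicate number. WT replicate 1 lies at 1.46 for cell cycle genes and -1.05 for adipocyte genes, towards the Nod2-/- libraries, and at -0.01 for keratinocyte genes, with the other WT libraries.

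Cell cycle genes formed the list with the smallest p. Of 35 members 29 rose, 35 when adjusted over the list alone, and edgeR called 17. The replicative helicase genes Mcm4 (437 ± 151 to 1754 ± 533), Mcm7 (405 ± 117 to 1130 ± 246.5) and Mcm3 (430.1 ± 183 to 1384 ± 297) rose. The list's median log2 fold change was 2.81, and 1.16 against WT replicate 1 alone. Its adjusted p was 1.24e-14 with limma's camera and adjusted p = 0.614 with an estimated correlation. The call also ended with the adipocyte score as a covariate (mean 0.0979 in place of 2.57, adjusted p 0.212; 4.85e-21 to 0.614 over all alternatives). Carcinoma and epithelial-mesenchymal genes had 7 of 25 members higher (10 higher and 2 lower adjusted over the list alone) and a median of 0.85, and 0.41 against WT replicate 1 alone. Vimentin (Vim) rose from 9053 ± 1449 to 18600 ± 1190, and the laminin-332 chains Lamb3 and Lamc2 rose by 1.82 and 3.54. The camera adjusted p was 0.00456, adjusted p = 0.614 with an estimated correlation and 0.338 with the adipocyte covariate (mean 0.191 in place of 0.837; 0.000513 to 0.614 over all alternatives).

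Matrix genes moved in both directions. Of 26 fibroblast and collagen genes 9 rose and 3 fell (12 and 4 adjusted over the list alone). Fibronectin (Fn1, 9570 ± 1686 to 26390 ± 1680) and Col5a2 (3544 ± 1092 to 9573 ± 1910) rose, while osteoglycin (Ogn, 4511 ± 1034 to 1355 ± 314.5) and dermatopontin (Dpt, 9935 ± 2333 to 3428 ± 1482) fell. Of 21 matrix proteases and inhibitors 8 rose and 1 fell (10 and 1 adjusted over the list alone; edgeR 3 and 1). Mmp14 (1510 ± 190 to 3460 ± 643), the aggrecanase Adamts4 and the plasminogen activator inhibitor Serpine1 rose by 1.18, 2.97 and 3.83, and Timp3 fell by 1.81. In WT replicates 1, 2 and 3 Adamts4 had 97.21, 12 and 23.8 normalised reads and Serpine1 865.69, 78 and 67.07. The Nod2-/- levels were 248.8 ± 44.87 and 2417 ± 566.5. Limma's camera gave the lists adjusted p values of 0.00924 and 0.0256, with adjusted p = 0.809 and 0.614 with an estimated correlation. The first camera call was lost without Nod2-/- replicate 1 (mean 0.169 in place of 0.393, adjusted p 0.114, and 2.03e-08 to 0.809 over all alternatives). The second was lost without WT replicate 3 (adjusted p 0.0678) and without Nod2-/- replicate 1 (0.147). It was also lost with scaling by library size (0.142), where the mean was 1.42 in place of 1.16 and so did not shrink. Over all alternatives the second list's adjusted p ran from 0.00589 to 0.614. The medians were 0.58 and 0.70, and 0.51 and 0.33 against WT replicate 1 alone.

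Of 29 hypoxia and glycolysis genes 8 rose and 2 fell (9 and 2 adjusted over the list alone), with a median of 0.36, and 0.50 against WT replicate 1 alone. The oxidoreductase gene Ero1l, Ndrg1, the glycolytic Pgk1 (2149 ± 328 to 4372 ± 292) and the prolyl hydroxylase gene Egln3 rose by 1.28, 1.10, 1.03 and 1.22. Camera gave an adjusted p of 0.0248, and adjusted p = 0.614 with an estimated correlation. It was 0.278 without WT replicate 1 and 0.1 without Nod2-/- replicate 1 (8.93e-10 to 0.614 over all alternatives). Skeletal muscle genes passed as a list although none of 29 members passed, over all genes or adjusted over the list alone (median 2.28, camera adjusted p 0.00693, adjusted p = 0.833 with an estimated correlation). The muscle scores spread widely within groups, from -3.02 to 2.88 in WT and from -0.26 to 5.05 in Nod2-/-. The mean was 2.19, but 0.685 without WT replicate 3 and 0.766 without Nod2-/- replicate 1, and the median was 3.79 without WT replicate 1. The muscle camera call was lost without WT replicate 3 (adjusted p 0.218) and without Nod2-/- replicate 1 (0.351). It was also lost with scaling by library size (0.185, mean 2.43) and with the adipocyte covariate (0.124, mean 1.36). The direction turned against WT replicate 1 alone (mean -0.69). Over all alternatives the adjusted p of the muscle list ran from 1.38e-12 to 0.833.

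Adipocyte genes were lower in Nod2-/- tumours. Of 26 members 21 fell, 25 when adjusted over the list alone, with a median of -2.40, and -1.47 against WT replicate 1 alone. The lipid droplet gene Cidec (15800 ± 2898 to 3139 ± 1450), resistin (Retn, 11500 ± 4557 to 2007 ± 757) and the lipase gene Pnpla2 (12320 ± 3880 to 2257 ± 1312) fell together with Cfd. Of 11 nerve and glia genes 9 fell (9 adjusted over the list alone; median -1.61, and -1.13 against WT replicate 1 alone), among them the Schwann cell factor Sox10 and S100b, with log2 fold changes of -2.99 and -2.12. Of 14 hepatocyte genes 8 fell and 1 rose (8 and 1 adjusted over the list alone; median -1.73, and -1.10 against WT replicate 1 alone), with Cyp2e1 at 35650 ± 8094 and 5327 ± 2321 and albumin (Alb) at 1366 ± 525 and 213.9 ± 108. Fat expresses several of these, Cyp2e1 and Trf included. In camera the adjusted p values were 7.84e-10, 9.45e-05 and 0.0023, each with adjusted p = 0.614 with an estimated correlation. The hepatocyte call was also lost with the adipocyte covariate (mean -0.0622 in place of -1.52, adjusted p 0.54; 2.39e-05 to 0.614 over all alternatives).

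Of 13 mitochondrially encoded genes 12 fell, 13 when adjusted over the list alone (median -0.94, and -0.83 against WT replicate 1 alone), with mt-Nd4l at 10320 ± 1376 and 4656 ± 207. Mitochondrial genes took 9.14%, 9.78% and 10.2% of the reads in WT and 6.07%, 5.52% and 5.5% in Nod2-/-, and the 10 most abundant genes 10.9%, 15.4% and 15.4% against 7.94%, 6.88% and 6.55%. Of 30 nuclear genes of oxidative phosphorylation 8 fell, 19 when adjusted over the list alone (median -0.52, and -0.23 against WT replicate 1 alone), for example Cox4i1 (4932 ± 576 to 2943 ± 238) and Ndufb3. In camera these lists had adjusted p values of 2.59e-06 and 8.79e-07, both with adjusted p = 0.614 with an estimated correlation. The second was 0.779 with the adipocyte covariate (mean -0.0478 in place of -0.578; 1.09e-08 to 0.779 over all alternatives). Of 7 red blood cell genes 4 fell (5 adjusted over the list alone), all of them globins (Hba-a1, Hba-a2, Hbb-bt and Hbb-bs, near-identical pairs whose reads can be split) with changes from -1.14 to -0.94 (list median -0.99, and -1.16 against WT replicate 1 alone). The camera adjusted p was 0.0248, adjusted p = 0.614 with an estimated correlation and 0.125 without WT replicate 1 (0.00278 to 0.614 over all alternatives).

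Keratinocyte genes were higher in every Nod2-/- library than in any WT library as a list, from several genes near the floor in WT. Of 14 members tested 12 rose (12 adjusted over the list alone), with a median of 4.25 (4.25 also with the 5 members at 0 reads in WT set to their bound), and 4.2 against WT replicate 1 alone. Krt1 had 2 reads in WT and 2231 in Nod2-/-, a ratio of 969 (95% counting interval 268 to 8010). The filaggrin gene Flg had a ratio of 228 (40.5 to 9030). Hornerin (Hrnr) and desmocollin 1 (Dsc1) had 0 reads in WT and were at least 40.5-fold and 20.1-fold higher in Nod2-/-, against a floor of 3 reads per library. Camera gave the keratinocyte list an adjusted p of 5.76e-10, and adjusted p = 0.614 with an estimated correlation.

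Genes of the resting mammary gland went the other way in part. Of 19 mammary epithelium and milk genes 9 fell and 2 rose (10 and 5 adjusted over the list alone), with a median of -1.31, and -1.20 against WT replicate 1 alone. Besides Csn3, the oxytocin receptor gene Oxtr fell from 729.7 ± 146 to 78.0 ± 6.08, the luminal keratin Krt19 from 1232 ± 62.2 to 328 ± 33.4 and the progesterone receptor gene Pgr from 297 ± 47.6 to 59.0 ± 9.94. Csn3 and Oxtr had the smallest adjusted p of all genes in limma (0.00384). The list's camera adjusted p was 0.0352, and adjusted p = 0.614 with an estimated correlation. This call was lost without WT replicate 1 (0.18), without Nod2-/- replicate 1 (0.116) and with the 1 CPM filter (0.0677; 5.67e-06 to 0.614 over all alternatives).

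**Figure D2:**
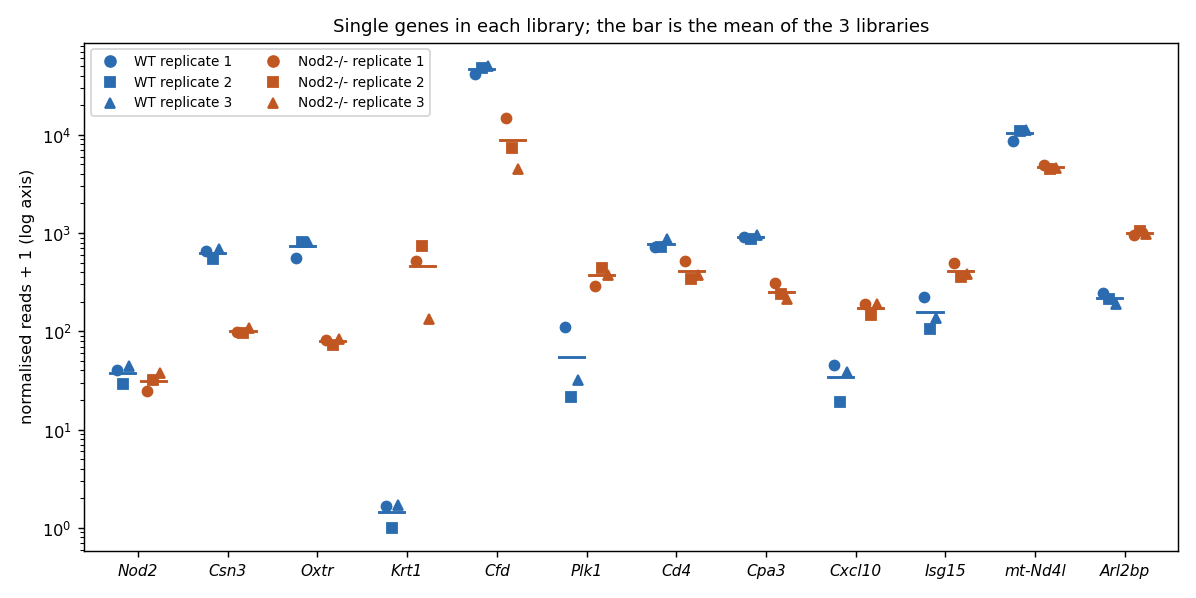
Normalised reads + 1 (vertical log axis) of 12 genes in each library, with the mean of each group's 3 libraries as a bar; colour is the genotype and shape the replicate number. All genes shown but Nod2 separate all WT from all Nod2-/- libraries, and WT replicate 1 lies towards the Nod2-/- libraries for Plk1.

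Interferon-stimulated genes were in part modestly higher in Nod2-/- tumours. Of 31 type I interferon genes 11 rose and 1 fell (12 and 1 adjusted over the list alone), with a median of 0.49, and 0.63 against WT replicate 1 alone. Ifi44 (290.1 ± 82.1 to 702.5 ± 140.1), Isg15 and Rtp4 (309.6 ± 28.9 to 506 ± 41.7) rose by 1.30, 1.46 and 0.71, while the member with the smallest p, Ifi27l2a, fell from 10350 ± 1183 to 3299 ± 832. Of 27 interferon gamma genes 4 rose (4 adjusted over the list alone; median 0.39, and 0.69 against WT replicate 1 alone): the chemokines Cxcl10 (33.2 ± 13.5 to 173 ± 23.8) and Cxcl11, and the GTPase genes Irgm1 and Iigp1. The camera adjusted p values were 4.26e-05 and 0.0023, with adjusted p = 0.614 and 0.706 with an estimated correlation. The second was 0.102 without WT replicate 1 (5.07e-08 to 0.706 over all alternatives).

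Inflammatory genes rose in part. Of 25 NF-kB target genes 6 rose (7 higher and 1 lower adjusted over the list alone; edgeR 3), with a median of 1.18, and 0.26 against WT replicate 1 alone. Nfkb1 (898 ± 72.4 to 1439 ± 195), the chemokine Ccl20 and the cytokine Lif rose by 0.67, 1.29 and 1.92. Of 16 genes of classically activated macrophages 5 rose (6 adjusted over the list alone; edgeR 3; median 1, and 0.44 against WT replicate 1 alone), among them the nitric oxide synthase Nos2 (27.3 ± 9.16 to 115 ± 37.2), Acod1 and the prostaglandin synthase Ptgs2 (173 ± 219 to 1147 ± 162). The camera adjusted p values were 0.000367 and 0.00101, both with adjusted p = 0.614 with an estimated correlation. The direction of the first turned with the adipocyte covariate (mean -0.46 in place of 1.37, adjusted p 0.061; 8.88e-06 to 0.614 over all alternatives). The second was 0.287 with that covariate (mean 0.209 in place of 1.49; 0.000144 to 0.614 over all alternatives).

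T cell and mast cell genes were lower in part. Of 25 T cell genes 8 fell and 1 rose (11 and 1 adjusted over the list alone; edgeR 5 and 1), with a median of -0.60, and -0.70 against WT replicate 1 alone. Cd4 (771 ± 88.2 to 407 ± 93.4), Cd3d (684 ± 22.6 to 396 ± 79.2), Cd3e (527 ± 54.1 to 259.7 ± 83.1) and Cd8b1 (426 ± 39.0 to 213 ± 70.4) fell. Of 15 mast cell, basophil and eosinophil genes 5 fell (6 lower and 1 higher adjusted over the list alone; median -0.67, and -0.97 against WT replicate 1 alone), with the mast cell proteases Cpa3 (914.5 ± 40.3 to 252 ± 49.8), Mcpt4, Tpsb2 and Cma1 at log2 fold changes of -1.87, -1.65, -2.09 and -1.90. Of 10 lymph node stroma genes 5 fell (6 lower and 1 higher adjusted over the list alone; median -1.10, and -1.03 against WT replicate 1 alone), among them Glycam1 (9965 ± 2605 to 3017 ± 526) and the chemokines Ccl21a and Ccl19. From camera the adjusted p values were 0.000125, 0.0185 and 0.0248, with adjusted p = 0.763, 0.614 and 0.614 with an estimated correlation. Mast cell genes lost the call without WT replicate 1 (mean -0.296 in place of -0.481, adjusted p 0.102; 3.91e-06 to 0.614 over all alternatives), and lymph node stroma without WT replicate 1 (0.0765) and without WT replicate 3 (0.0526; 0.00581 to 0.614 over all alternatives).

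The other myeloid and lymphoid lists did not pass camera. Median and mean log2 fold changes differed in sign for macrophage (-0.10 and 0.09), neutrophil (-0.37 and 0.14), NK (-0.06 and 0.11), NOD2 pathway (0.17 and -0.02) and immediate early genes (-0.02 and 0.24). The alternatively activated macrophage list (adjusted p 0.127) had 5 of 16 members lower (5 adjusted over the list alone): Retnla fell from 5055 ± 2121 to 884 ± 376 and Mgl2 from 1062 ± 204 to 336 ± 57.7. Macrophage and monocyte genes (0.912) had 1 higher and 3 lower of 20 (1 and 3 adjusted over the list alone), with the chemokine receptor gene Cx3cr1 up by 2.06 and the efferocytosis receptor gene Mertk down by -1.31. Neutrophil genes (0.912) had 3 higher and 7 lower of 28 (4 and 7 adjusted over the list alone), with lactoferrin (Ltf) down by -2.74 and the stefin genes Stfa1 and Stfa3 up by 4.27 and 5.89. Stefin genes are close copies, so their reads can be split. Dendritic cell genes (0.408) had 1 higher and 2 lower of 18 (1 and 2 adjusted over the list alone), with Siglech down by -1.66. B cell and plasma cell genes (0.408) had 3 lower of 19 (3 adjusted over the list alone), with Ighg1 down by -2.58. Cytotoxic genes (0.722) had 2 higher and 2 lower of 16 (2 and 2 adjusted over the list alone), with Gzme up by 3.62 and Prf1 down by -1.01. NK genes (0.839) had 1 higher and 1 lower of 13 (1 and 1 adjusted over the list alone), the lower being the mast cell chymase Cma1. Regulatory T cell and checkpoint genes (0.47) had 2 higher and 1 lower of 17 (1 and 1 adjusted over the list alone), with Tnfrsf9 up by 1.25 and Lag3 down by -1.22.

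Antigen presentation, pathway and control lists did not pass either. MHC class II genes (0.762) had 0 of 13 members past limma's threshold, over all genes or adjusted over the list alone (H2-Eb1 -0.56, adjusted p 0.0849; 1.45-fold lower level). MHC class I genes (0.255) had 4 of 18 lower (5 adjusted over the list alone), with H2-K1 at 5173 ± 408 and 3389 ± 161. The NOD2 pathway (0.547) had 1 higher and 2 lower of 32 (1 and 0 adjusted over the list alone): Irgm1 rose by 0.89, while Nod1 and Pglyrp1 fell (-0.98 and -0.93). Chemokines (0.274) had 6 higher and 8 lower of 33 (9 and 9 adjusted over the list alone), with Cxcl11 up by 3.07 and Ccl5 down by -1.37. Complement (0.0659) had 1 higher and 4 lower of 20 (1 and 4 adjusted over the list alone), with C3 down by -1.63. Endothelial genes (0.526) had 2 higher and 3 lower of 26 (2 and 3 adjusted over the list alone), with Apln up by 1.84 and Cldn5 down by -1.62. The unfolded protein response (0.516) had 3 lower of 20 (2 adjusted over the list alone), with Xbp1 down by -0.79, and apoptosis and p53 targets (0.533) had 2 higher and 1 lower of 19 (1 and 0 adjusted over the list alone), with Tnfrsf10b up by 1.91. Immediate early and heat shock genes (0.912) had 2 higher and 1 lower of 23 (3 and 5 adjusted over the list alone), with Ier3 up by 1.84. Of 35 ribosomal protein genes (0.722) 0 passed, over all genes or adjusted over the list alone. Of the sex-linked list only Xist was tested, and it fell from 5787 ± 991 to 3209 ± 538.

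The largest increases among genes with clear expression included Krt1, the chromatin protein gene Hmga2 (178 ± 305 to 1839 ± 359), Stfa3, Glrp1, tenascin N (Tnn, 3.33 ± 2.64 to 181 ± 106), the AP-1 gene Fosl1, the epidermal calmodulin Calm4, Nptx1, the collagenase Mmp13, Col12a1 (425 ± 545 to 6986 ± 835), Crabp1 and tenascin C (Tnc, 1089 ± 1517 to 10420 ± 1150), with log2 fold changes from 4.36 for Tnc to 8.04 for Krt1. The largest decreases were in Angptl8 (425 ± 586 to 6.47 ± 5.98), Inmt, the milk fat globule gene Btn1a1, Clic6, Mid1 (786 ± 254.5 to 52.8 ± 15.8), Cyp2f2, angiotensinogen (Agt), Mmd2, the myelin gene Mpz, Atp6v1b1, Cldn22 and Mup3, from -4.97 for Angptl8 to -3.31 for Mup3. edgeR did not call 6 of these 12 increases, Hmga2 (log2 fold change 3.39, adjusted p 0.174), Glrp1 (3.03, 0.151), Fosl1 (3.30, 0.111), Mmp13 (3.32, 0.093), Tnc (3.29, 0.0673) and Nptx1 (3.95, 0.0579), and called 12 of the 12 decreases. Other named genes that limma called and edgeR did not were Gzme, Prf1, Ptgs2, Pglyrp1, Lif, Serpine1, Lamc2 and Zfp423 (adjusted p from 0.0537 to 0.0807). Mup3, Cldn22 and Mid1 have close copies or overlapping neighbours, so their counts are uncertain. The SD in WT exceeded the mean for Hmga2, Glrp1, Fosl1, Nptx1, Mmp13, Col12a1, Crabp1, Stfa3, Tnc and Angptl8. WT replicates 2 and 3 had at most 5.77 normalised reads for Hmga2, Glrp1, Fosl1, Nptx1 and Mmp13. WT replicate 1 had 530.71, 93.93, 78.16, 40.07 and 137.28, and the lowest Nod2-/- library 1423.85, 156.4, 167.44, 107.56 and 275. Their log2 fold changes thus rest mostly on WT replicates 2 and 3. Angptl8 had 1100.5 in WT replicate 2, against 51.89 and 122.61 in WT replicates 1 and 3.

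The genes around Nod2 did not move as a list (22 tested, 2 higher and 4 lower, 2 and 4 adjusted over the list alone; camera adjusted p 0.924). Tox3, Lonp2 (2535 ± 960 to 1013 ± 95.4) and Zfp423 fell, with log2 fold changes of -1.87, -1.24 and -2.04, and Heatr3 rose by 0.57. Within 10 Mb, 41 of 176 tested genes passed (23.3%, against 21.3% elsewhere). Arl2bp, singled out after its values were seen, lies 5.98 Mb from Nod2 and rose from 217 ± 29.4 to 995 ± 48.7 (log2 fold change 2.20, SE 0.151, limma adjusted p 0.00455), the gene of rank 5 by p among all tested.

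**Figure D3:**
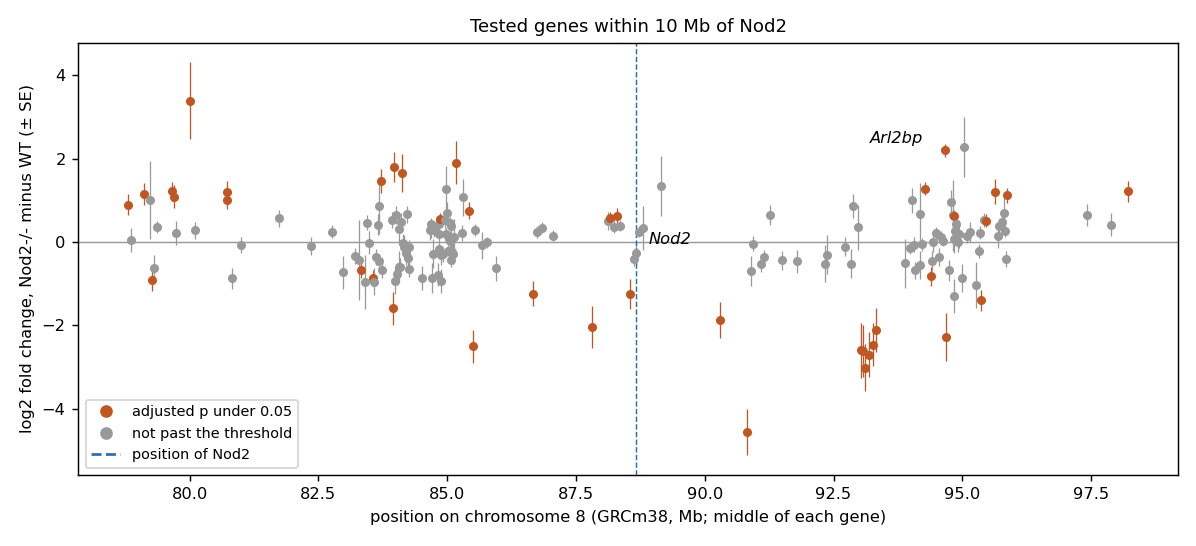
Log2 fold change of Nod2-/- minus WT (vertical axis, bars ± SE) of the 176 tested genes within 10 Mb of Nod2 by position on chromosome 8 in Mb (horizontal axis); coloured points passed limma's threshold. Arl2bp stands at 2.20 and Nod2 at -0.27.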

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

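Tests with TMM factors for limma, pseudocounts of 0.5 and 5, WT replicate 1 alone and the adipocyte covariate were chosen after the results were seen. The same holds for the earlier symbol matching. edgeR, the test planned for raw counts, became an alternative on the recovered reads. The count of 3852 genes lay between 3317 and 4818 under the other scalings, filters, pseudocounts, edgeR and limma-voom. The count was 5531 with DESeq2, whose calls held the most false ones in the simulation of independent genes. It was 2546 with an absolute log2 fold change of at least 1 and 6676 at a threshold of 0.1, by construction of those settings. Leaving out each library in turn gave 0 to 7682 genes, with fewer samples in the fit, and WT replicate 1 alone gave 0, in a fit whose spread comes from the Nod2-/- libraries only. With the adipocyte score as a covariate limma called 17 genes, all lower (1274 at an unadjusted p under 0.05); the scores of the groups do not overlap and the fit loses a degree of freedom, and this setting gives no value for the adipocyte list itself. The replicate block gave 0 genes (5892 at an unadjusted p under 0.05). Libraries with the same number deviated with correlations of -0.165, -0.0734 and 0.0907, and 1 of the 3 WT libraries correlated best with its own number. These few values show no pairing by number but cannot exclude it. No label says whether libraries with the same number share a litter or batch. Nod2 kept its direction and stayed short of the threshold throughout, between -0.80 and -0.02. Of the 119 named genes that passed, edgeR kept 105 and scaling by library size 108; 119 kept their sign under the 4 other scalings. The 21 lists were 17 to 24 in all settings but 2: 0 lists passed camera with an estimated correlation (40 lists, smallest adjusted p 0.614) and 5 passed fry, while 36 passed fry's mixed test. The 5 in fry were mammary epithelium (fry adjusted p 0.00324), mitochondrially encoded (0.00397), keratinocyte (0.00767), mast cell (0.025) and nerve and glia genes (0.025). Cell cycle and adipocyte genes did not pass fry (0.0728 each). Depth limits Krt1, Flg, Hrnr and Dsc1, which rest on 0 to 2 WT reads; no comparison at matched depth was run.

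Turned directions are given as the list's mean log2 fold change, direction being that of camera against other genes; the cause was not tested. None of these lists passed in the setting shown and in the main test together, but some passed camera at the preset correlation in the setting alone. With the adipocyte covariate these were ribosomal proteins (adjusted p 9.83e-17), endothelium (0.000233), chemokines (0.0185) and the neighbours of Nod2 (0.0435). With an estimated correlation 0 of 40 lists passed in the main fit (ribosomal proteins 0.967). With scaling by library size the turned lists were NK (0.354), MHC class II (0.191), immediate early genes (0.494) and neighbours of Nod2 (0.00347), and with the 1 CPM filter the neighbours of Nod2 (-0.177). The replicate block turned macrophages (0.09), and fry turned immediate early genes (0.24). Without single libraries the ranges were 0.203 to 0.485 for cytotoxic genes, -0.121 to 0.283 for NK, -0.559 to -0.0703 for B cells, -0.0582 to 0.368 for macrophages, -0.407 to 0.495 for neutrophils, -0.26 to 0.0568 for MHC class II, -0.533 to -0.0267 for endothelium, 0.147 to 0.395 for immediate early genes, -0.125 to 0.288 for ribosomal proteins and -0.377 to -0.177 for the neighbours of Nod2. Against WT replicate 1 alone NK (-0.237), B cells (-0.158), chemokines (-0.123), endothelium (-0.108), skeletal muscle (-0.686), ribosomal proteins (-0.514) and the neighbours of Nod2 (-0.00823) turned. With the adipocyte covariate the genes Hmga2 (-0.577), Glrp1 (-0.971), Fosl1 (-0.434), Mmp13 (-0.596), Lif (-0.135) and Timp3 (0.108) turned, as did cytotoxic genes (-0.063), NK (-0.587), regulatory T cell genes (-0.381), MHC class II (0.157), the NOD2 pathway (-0.0923), NF-kB targets (-0.462), chemokines (-0.504), complement (0.0852), endothelium (0.509), apoptosis (-0.0144), ribosomal proteins (-0.778) and the neighbours of Nod2 (0.168).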

Other observations

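The count of splits and the scalings other than TMM were planned; the bound set on the scalings and the other tests below were chosen after the results were seen.

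Epidermal and pigment cell genes, singled out after their values were seen, differed between the Nod2-/- libraries. The cornified envelope gene Lor had 21.5, 110.2 and 10.4 normalised reads in Nod2-/- replicates 1, 2 and 3, and Krt77 had 105, 611 and 1.39, against at most 1.71 and 6.57 in WT. Hair follicle keratin and trichohyalin genes (Krt25, Krt27, Krt71 and Tchh) had 12, 9 and 28 reads in WT and 20, 11 and 10 in Nod2-/-. Melanocyte genes (Tyrp1, Dct, Pmel and Mlana) had 34, 88 and 64 reads in WT and 12, 29 and 17 in Nod2-/-.

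The first pattern is the joint rise of cell cycle genes and fall of adipocyte genes among 3852 called genes. Of the 10 splits of the 6 libraries, 1 (the real one) gave that many and the highest other gave 0, but 10 splits cannot give a share under 0.05. The authors' scaling is argued against as the cause of the count alone, since 4 other scalings left at least 3909. A count does not test direction: scaled by library totals, 69.9% of called genes were higher in Nod2-/- in place of 44.4%, and 3158 of the 3852 stayed called. That WT replicates 2 and 3 held more fat pad and fewer carcinoma cells is a candidate explanation that stays open: on a scale from their mean (0) to the Nod2-/- mean (1), WT replicate 1 lay at a median of 0.626 over 29 called cell cycle genes (quartiles 0.543 and 0.687) but 0.445 over 21 adipocyte genes (0.369 and 0.593), and its place between the groups was what prompted the explanation. Among the largest increases Hmga2 had 1.71 and 2.16 normalised reads in WT replicates 2 and 3 but 530.71 in WT replicate 1. Fosl1 had 0 and 1.44 there but 78.16 in WT replicate 1. Krt1, Tnn and Calm4 were low in all WT libraries (at most 6), so these picked genes do not decide the explanation. The type I interferon list stays open too: with the adipocyte score as a covariate the list's mean log2 fold change went from 0.477 (SE 0.122) to 0.637 (SE 0.266 on 3 degrees of freedom, 95% interval -0.209 to 1.48), with camera adjusted p 1.18e-09 at the preset and 0.671 at an estimated correlation, while the mean of cell cycle genes went from 2.57 (SE 0.774) to 0.0979 (SE 0.801) and lost the call. Whether the tissue share differs at all stays open, and whether it would do so through how tumours were cut out or through the host genotype was not tested.

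The second pattern is the rise of keratinocyte genes. The size of the rise does not decide the fat pad explanation. The lower quartile of the 14 keratinocyte log2 fold changes (3.33, with genes at 0 WT reads at their bound) lay above the upper quartiles of cell cycle (3.11) and carcinoma genes (1.26). But 5 members with 0 WT reads passed the filter through Nod2-/- reads alone. Hmga2 and Fosl1, which were present in WT replicate 1, rose by 6.77 and 5.45. On the scale of the first pattern WT replicate 1 lay at a median of 0 over 12 called keratinocyte genes (quartiles 0 and 0.0474). That is with the other WT libraries, where several of these genes were near the floor. Epidermis in the Nod2-/- tumour pieces may add these transcripts: the ratio of Lor, Krt77 and Krt2 to Krt10 differed 11.2 times between the Nod2-/- libraries (0.234, 0.586 and 0.0522), which a single kind of skin would not give, yet skin pieces of different make-up or squamous differentiation in the tumour could. Hair follicle and melanocyte genes were not higher in Nod2-/-, but resting follicles lack such keratins, so skin and a change in the tumour's own cells cannot be told apart here. An effect of the genotype stays open as well.

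The third pattern is Arl2bp, 5.98 Mb from Nod2, with little spread within groups. WT replicate 1 lay at 0.129 on the scale used for the first pattern, but the gene was picked for its small spread, so this does not decide the fat pad explanation. DNA of another strain kept around the knocked-out Nod2 could change neighbouring genes; the share of called genes within 10 Mb was higher than in 69.7% of 1428 runs of equally many genes elsewhere, which leaves it open, and 35 of 170 passed without the Ces1 cluster of close copies. The labels do not give the strain of the cells used to make the knockout. A direct effect of Nod2 on Arl2bp was not tested.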
